A study of Mus musculus and Rattus norvegicus with 36 samples.

How the data were processed

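The values analysed are those of the 5 gene tables the authors deposited, whose unit is a signal: read counts divided by 1 factor per sample, so that 1 read is worth between 0.9052 and 1.117 of a unit, depending on the library. In all 36 columns 100% of the nonzero values are whole multiples of the smallest step within a tolerance of 1e-06. Per the submitters' processing notes the tools were HISAT, Bowtie2 and DESeq2 and the mouse build was GRCm38.p6; the notes give no versions and do not say what each tool was used for. The rat build is not given in the sources used here. Libraries were made from poly-A RNA and read as single 50-base reads on a DNBSEQ machine, per the labels. Because the tables hold scaled values rather than raw counts, a count test was not run: the plan had foreseen edgeR quasi-likelihood for tables of raw counts only, and it was not used.

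The 5 tables hold the 12 acutely isolated mouse libraries, the mouse mPFC cultures, the mouse hippocampus cultures, the rat cultures of the GABA set and the rat cultures of the glutamate set. The acute table has 22,064 entries, of which 3600 carry no values and 18,464 were kept. The mouse culture tables keep 26,349 of 26,432 entries (mPFC) and 26,410 of 26,491 (hippocampus) after identical repeats were removed. The rat tables keep 16,263 of 19,322 and 16,437 of 19,609 entries; 2797 and 2915 entries without a gene symbol, which hold 1.52% to 1.66% of the reads, were left out. Group, region, treatment and genotype come from the labels alone. Acute tissue is labelled mPFC on every such sample, while the extraction protocol speaks of dissecting cortex; the sample label was used. The knockout hippocampus replicates are numbered 4 to 6 in their titles and 1 to 3 in their descriptions, and the titles' numbers are used in the text.

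Values were taken as log2(value + 1) and compared with limma-trend, 1 fit per table, with a coefficient per group. A gene was tested where its value is at least 10 in at least 3 of all samples in the fit. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, and a gene passed at an adjusted p under 0.05. Fold changes are on the log2 scale with the pseudocount of 1 included, which understates changes of genes near the lower limit. Errors after a fold change are standard errors of the limma coefficient, errors after a group mean are standard deviations, and every group has 3 libraries. Tables were normalized separately. The comparisons that join tables (the GABA effect between mouse regions, and glutamate against GABA in rat) therefore use only differences taken inside each table. With 3 against 3 libraries an exact permutation of labels cannot give a p below 0.10, so all smaller p-values rest on the variance model shared between genes.

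In the text a gene rose or fell if it passed. The genes named are Smarcc1 in the knockout comparisons; the 8 largest rises and the 8 largest falls of a comparison, among genes that passed, whose replicates do not overlap between the groups (not asked of the differences between effects), whose higher group mean is at or above the median of the tested genes, and whose symbol is not provisional; and, for a described list, 2 to 4 members with the smallest p-values. Not every gene this rule selects is printed. Some genes are not reported here, though they are counted in the totals and lists. Coordinates are those of GRCm38 with GENCODE M21 gene models, the build the submitters name, and were used for gene positions, gene length and GC content only.

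29 gene lists were written from textbook knowledge: OPC markers, committed OPC, myelin and oligodendrocyte, microglia, astrocyte, neuron, endothelial, mural and fibroblast, ependymal and choroid plexus, blood, BAF subunits without Smarcc1, glutamate receptors, GABA receptors, transmitter transport and metabolism, cell cycle, cholesterol synthesis, immediate early, heat shock, integrated stress and unfolded protein response, p53 targets, interferon, hypoxia and glycolysis, autism risk, synaptic adhesion, Wnt targets, Notch pathway, forebrain regional transcription factors, mitochondrially encoded, and ribosomal proteins. A list was tested where at least 5 members were. Lists were tested with camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, adjusting over the lists of a comparison. The preset is the planned test, and the estimate is given wherever it takes a result away. Gene counts of a list come from the adjustment over all genes, and a count adjusted over the list alone is given beside them.

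Comparisons, lists, filter, pseudocount and the alternatives were fixed before the data were examined. The alternatives are pseudocounts of 0.1 and 10, no filter, median-of-ratios rescaling, quantile normalization, robust empirical Bayes, only the groups of a contrast in the fit, replicate number as a block, and each library left out in turn. Chosen after the data were seen were the knockout effect averaged over both regions, the region axis, the crossing of control labels with and without a replicate block, the Cochran Q over microglia genes (weights 1 over the squared standard error), and the removal of knockout mPFC library 3 together with control hippocampus library 3. The region axis of an acute library is the slope of its log2 values, centred on the mean of all acute libraries, on the difference between untreated hippocampus and untreated mPFC cultures, so that a score is a fraction of the culture difference. It uses the 10,864 genes shared with the acute table whose mean culture log2 value is above 6. Because the culture tables were normalized separately, that difference was centred on its median.

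Scripts were first tested on simulated values with 200 changed genes and an excess coefficient of variation of 0.04. The first bar, over 80% of 2-fold genes recovered, was missed by the GABA difference between mouse regions, at 78.8% (33.3% of 21 low genes). The bar was then replaced by one on genes with a simulated mean of at least 100: 95% recovered, under 1% false calls, and a median estimated-over-true ratio within 0.1 of 1. All 12 comparisons met it, with 100% recovered at 2-fold, ratios from 0.989 to 1.017 and 0.01% to 0.09% false calls. Of all 1.2-fold genes 20.9% to 71.6% were recovered. Measured excess variation reaches 9.88% (knockout mPFC), so these rates may not hold here. Calls on low genes or small changes are thus less complete, most of all in the differences between effects.

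Xist is not among the tested genes of the acute table, and the tests planned on it were not analysed here. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.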

Results

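The series holds 36 poly-A libraries of oligodendrocyte precursor cells (OPCs), 12 groups of 3. 12 are from cells isolated acutely from mouse medial prefrontal cortex (mPFC) or hippocampus, taken from animals in which Pdgfralpha-CreER deletes Baf155 (gene symbol Smarcc1) or from littermates without Cre. Another 12 are cultured mouse OPCs of either region, untreated or given 200 uM GABA for 24 h. The last 12 are cultured rat cortex OPCs in separate sets, 1 with and without GABA and 1 with and without 200 uM glutamate. Taking the smallest step of a library as 1 read, depth runs from 14.9 to 22.1 M reads, and the 10 most abundant genes take 3.56% to 10.57% of them. The median fold change over all genes is near 0 in every comparison, so rises and falls below are relative to the other genes of the table. Nothing in the labels says that replicates are separate animals or cultures, so the p-values measure only the spread between these samples.

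Smarcc1 encodes a core subunit of the BAF chromatin remodeling complex, and its transcript was lowered but not absent in the knockout OPCs (chromosome 9: 110,117,708 to 110,240,178, plus strand, GRCm38). In the mPFC its level went from 3880.1 ± 57.2 in control libraries to 2465.1 ± 159 in knockout libraries, a fold change of −0.66 ± 0.05 on the log2 scale (adjusted p = 6.62e-08, n = 3 per group). In the hippocampus it went from 4462.2 ± 47.9 to 1570.2 ± 60.4, or −1.51 ± 0.05 (adjusted p = 1.4e-11). The loss was deeper in the hippocampus, by −0.85 ± 0.07 (adjusted p = 9.5e-07). With the region labels of the control groups exchanged, an alternative added after the data were seen, the difference is −0.45 ± 0.07. In culture Smarcc1 stood at 4515.8 ± 85.8 untreated and 4374 ± 155.2 with GABA (mouse mPFC), and at 4347 ± 91.4 and 4446.4 ± 103.8 (mouse hippocampus). In rat it stood at 3777.1 ± 52.6 untreated and 3619.8 ± 35.7 with GABA, and at 5225.8 ± 139.5 untreated and 5103.1 ± 96.1 with glutamate. Levels are comparable only inside a table. The deleted exons and the protein were not analysed here.

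Scg2, Vgf and Egr1 were far higher in knockout OPCs of the mPFC than in control OPCs. Scg2, which encodes a granin of dense-core vesicles, went from 70.3 ± 7.5 to 2364.2 ± 148.3 (log2 fold change 5.06 ± 0.08, adjusted p = 3.15e-15; chromosome 1: 79,434,669 to 79,440,120, minus strand). Vgf, a neurotrophin-induced secretory gene, went from 120.7 ± 4.3 to 1503.9 ± 265.6 (3.61 ± 0.10). The transcription factor gene Egr1, a rapid target of MAP kinase signaling, went from 2154 ± 43.7 to 15,041.5 ± 754.5 (2.80 ± 0.05, adjusted p = 3.15e-15). Falling furthest among the abundant genes were Alb, which encodes serum albumin, from 905.4 ± 38.6 to 104.2 ± 31.8 (−3.15 ± 0.50, adjusted p = 0.000114), and the Notch target Hes5, from 865.7 ± 51.7 to 207.4 ± 41.9 (−2.08 ± 0.14, adjusted p = 1.58e-08). Pde3a (2.30 ± 0.08), Sorcs2 (1.90 ± 0.10), Rorb (1.79 ± 0.09), Tubb6 (1.78 ± 0.09) and Ubash3b (1.72 ± 0.07) also rose. Tmem100 (−1.72 ± 0.07), the Notch ligand gene Dll3 (−1.48 ± 0.10), Dmrta1 (−1.40 ± 0.08), Rftn2 (−1.37 ± 0.05), Pnlip (−1.36 ± 0.06) and C1ql1 (−1.36 ± 0.09) fell. With exchanged control labels Alb loses the call at 0.71 ± 0.50, and Tmem100 (−0.94), Pnlip (−0.36) and Ubash3b (1.00) move by over 1.5 times. In all, 6622 of 13,985 tested genes passed, 3374 up and 3248 down, of which 343 and 293 changed at least 2-fold. The test is limma-trend on 3 against 3 libraries. Non-Cre littermates are the only control, so effects of Cre itself are not separated from loss of Baf155.

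Sterol genes fell almost without exception in the knockout mPFC. Of 24 genes of cholesterol synthesis 0 rose, 23 fell and 1 did not pass (23 adjusted over the list alone, camera adjusted p = 3.63e-14), among them the lanosterol synthase gene Lss (−0.76 ± 0.04), Insig1 (−0.95 ± 0.04) and Fdft1 (−0.62 ± 0.04). Cell cycle genes rose: 27 of 35, with 1 falling and 7 not passing (28 adjusted over the list alone, adjusted p = 2.1e-10), including Ccnd1 (0.94 ± 0.04), which drives entry into S phase, and the replication licensing genes Mcm4 (0.93 ± 0.04) and Mcm2 (1.09 ± 0.06). Among 17 p53 targets 9 rose, 0 fell and 8 did not pass (9 adjusted over the list alone, adjusted p = 0.00136), led by the cell cycle inhibitor gene Cdkn1a (1.30 ± 0.05) and Aen (0.90). Of 26 immediate early genes 15 rose, 5 fell and 6 did not pass (21 adjusted over the list alone, adjusted p = 0.000477), with Fosl2 at 1.57 and Fos at 1.31 ± 0.06. Heat shock genes rose in 6 of 10 cases with 0 falling and 4 not passing (6 adjusted over the list alone, adjusted p = 0.00219), led by Hsph1 (0.77 ± 0.05). So did 12 of 23 integrated stress and unfolded protein genes, with 2 falling and 9 not passing (15 adjusted over the list alone, adjusted p = 0.000613), among them Slc7a1 (0.90 ± 0.05) and the chaperone gene Hspa5 (0.66 ± 0.05). OPC markers fell: of 16, 3 rose, 11 fell and 2 did not pass (14 adjusted over the list alone, adjusted p = 0.00136), among them Matn4 (−1.69 ± 0.10) and Sox8 (−0.71 ± 0.04). Matn4 is at −0.56 and Fos at 1.99 with exchanged labels.

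Some groups in the knockout mPFC libraries belong to other cell types. Astrocyte genes rose in 11 of 15 cases, with 4 falling and 0 not passing (15 adjusted over the list alone, adjusted p = 0.00377), among them Aldh1l1 (1.23 ± 0.06) and Gfap (0.82 ± 0.06). Mural and fibroblast genes rose in 6 of 13 cases, with 0 falling and 7 not passing (6 adjusted over the list alone, adjusted p = 0.00518), led by Tagln (1.34 ± 0.11) and Col3a1 (1.27 ± 0.12). With exchanged control labels that list is lost at adjusted p = 0.237, its median going from 0.649 to 0.131, Tagln loses the call (0.12), and Aldh1l1 (0.29), Gfap (2.22) and Slc6a11 (0.32) move by over 1.5 times. Transmitter transport and metabolism genes (9 up, 2 down, 8 not passing of 19, 11 adjusted over the list alone, adjusted p = 0.0171) include the GABA transporter gene Slc6a11 (1.01 ± 0.04), and this result is lost at adjusted p = 0.151 with an estimated correlation and at 0.242 with exchanged labels. Wnt targets (6 up, 2 down, 2 not passing of 10, 8 adjusted over the list alone, adjusted p = 0.0209) include Nkd1 (1.39 ± 0.08) and are lost at adjusted p = 0.0725 with an estimated correlation, but pass so with exchanged labels (0.0234). Ribosomal protein genes (2 up, 35 down, 44 not passing of 81, 37 adjusted over the list alone, adjusted p = 5.63e-05) are lost at adjusted p = 0.446 with an estimated correlation, and turn direction with exchanged labels (25 up, 1 down, adjusted p = 0.000392). These counts are for lists written in advance, and the remaining lists did not pass as groups, though with exchanged labels synaptic adhesion (adjusted p = 0.00179) and committed OPC (0.00268) do. There BAF subunits (0.0435), hypoxia and Notch (0.0453 each) are lost at adjusted p = 0.148, 0.352 and 0.302 with an estimated correlation. Autism risk genes had 16 up, 10 down and 21 not passing of 47 (26 adjusted over the list alone, adjusted p = 0.287), and BAF subunits without Smarcc1 had 7 up, 6 down and 16 not passing of 29 (13 adjusted over the list alone, adjusted p = 0.809). Glutamate receptors had 7 up, 10 down and 7 not passing of 24 (adjusted p = 0.6). GABA receptors had 3, 5 and 8 of 16 (0.577), synaptic adhesion 4, 10 and 11 of 25 (0.196), committed OPC 5, 6 and 4 of 15 (0.353), and myelin 6, 6 and 5 of 17 (0.502). Microglia had 5, 0 and 10 of 15 (0.349), endothelial 4, 0 and 3 of 7 (0.196). Ependymal and choroid had 0, 3 and 3 of 6 (0.287), blood 2, 0 and 4 of 6 (0.485), and Notch 3, 6 and 4 of 13 (0.135). Hypoxia and glycolysis had 7, 0 and 11 of 18 (0.121), and forebrain regional transcription factors 7, 4 and 6 of 17 (0.287). Neuron genes had 8, 6 and 3 of 17 (0.681), with a median of −0.05 and a mean of −0.34 while the test points up. Interferon genes had 2, 3 and 6 of 11 (0.577), with a median of −0.23 and a mean of 0.04.

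**Figure D1:**
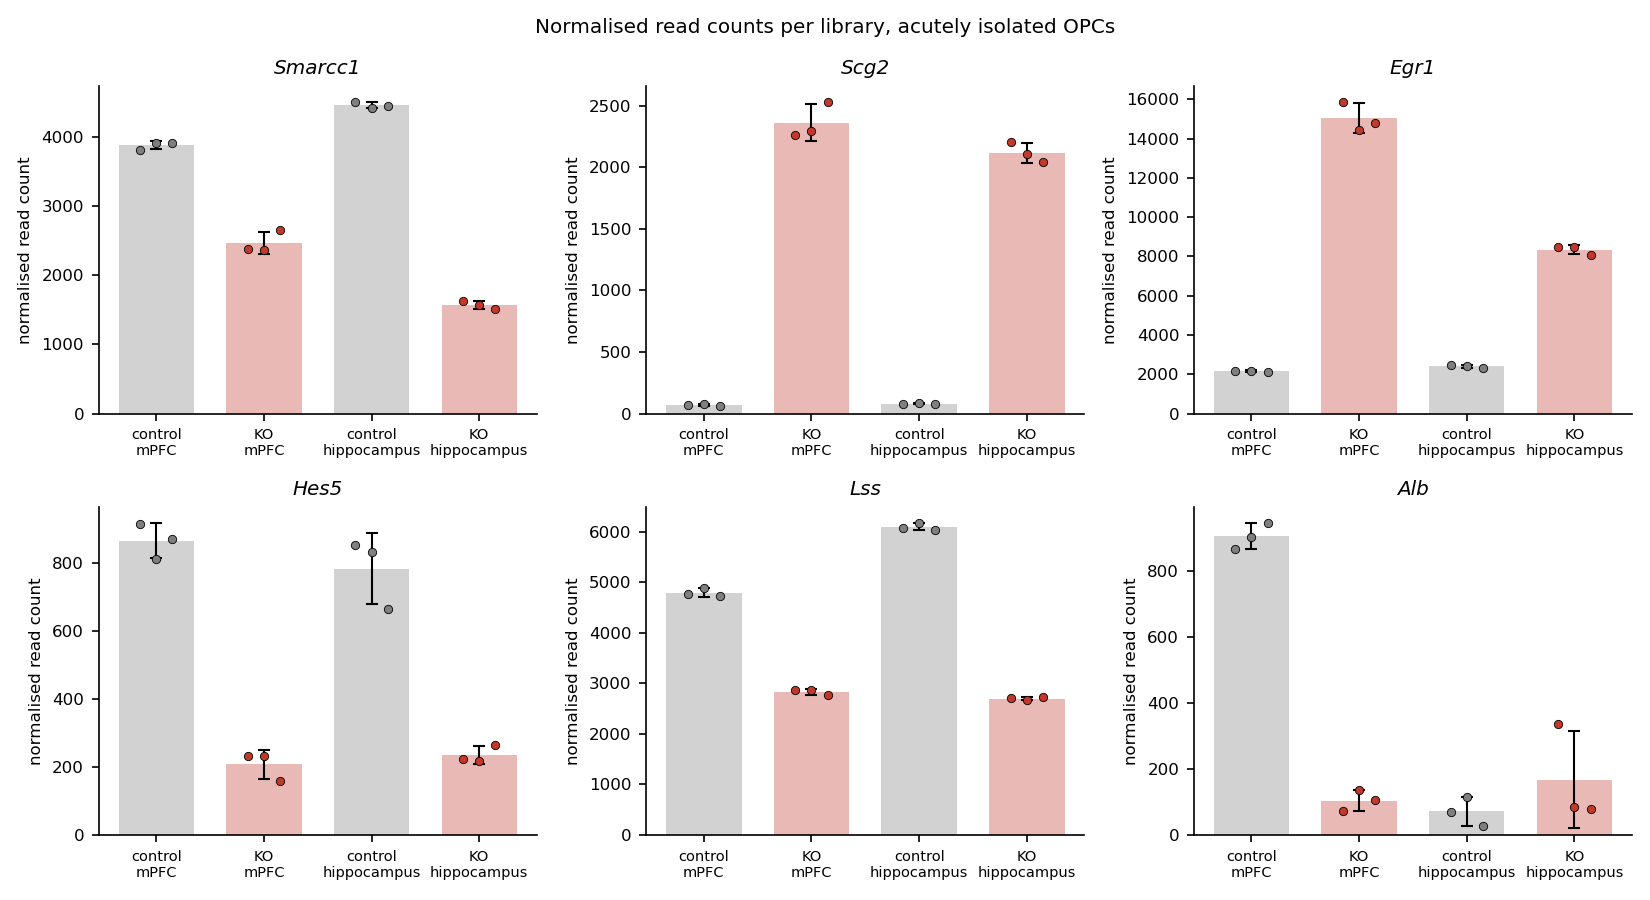
Levels of Smarcc1, Scg2, Egr1, Hes5, Lss and Alb (y axis, normalized read count) in the acute control and knockout groups of mPFC and hippocampus. Bars are means of 3 libraries, error bars standard deviations and points single libraries; Scg2 stands at 70.3 and 2364.2 in mPFC and at 79.2 and 2118.9 in hippocampus.

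In the hippocampus too Scg2 and Vgf were far higher in knockout OPCs, and Gfap rose with them. Scg2 went from 79.2 ± 3.2 to 2118.9 ± 81.1 (4.73 ± 0.08, adjusted p = 1.15e-14), and Vgf (chromosome 5: 137,026,392 to 137,033,351, plus strand) rose by 4.49 ± 0.10. Gfap, an intermediate filament gene of astrocytes and glial progenitors, went from 1269.6 ± 89.3 to 5051.1 ± 85.7 (1.99 ± 0.06, adjusted p = 3.05e-12), and Egr1 (chromosome 18: 34,859,823 to 34,864,984, plus strand) from 2410 ± 72.5 to 8346.4 ± 223 (1.79 ± 0.05). The lysozyme gene Lyz2, a marker of myeloid cells, went from 1705 ± 36.1 to 295.2 ± 11.5 (−2.53 ± 0.06, adjusted p = 2.74e-13), and Gpnmb fell by −2.01 ± 0.06. Hes5 (chromosome 4: 154,960,923 to 154,962,371, plus strand) went from 783.2 ± 103.7 to 234.9 ± 25.9 (−1.73 ± 0.14, adjusted p = 1.75e-07) and Dll3 fell by −1.69 ± 0.10. Syt4 (2.67 ± 0.11), Pde3a (2.42 ± 0.08), Hopx (1.82 ± 0.06) and Nkd1 (1.68 ± 0.08) rose as well, and the matrix gene Fbln2 (−1.64 ± 0.07), Atp10b (−1.50 ± 0.08) and Trp53i11 (−1.40 ± 0.07) fell. Under exchange Gfap is at 0.59, Gpnmb at −1.11, Hopx at 0.97, Fbln2 at −0.50 and Trp53i11 at −0.51. In all 5964 of 13,985 genes passed, 3029 up and 2935 down, with 274 and 216 at least 2-fold. The test is limma-trend on 3 against 3 libraries, and the mPFC limits apply.

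Sterol genes fell in the hippocampus too. Of 24 cholesterol synthesis genes 0 rose, 23 fell and 1 did not pass (23 adjusted over the list alone, camera adjusted p = 2.54e-21), with Lss at 2697.6 ± 32.3 against 6091.4 ± 68.1 in control (−1.18 ± 0.04), Insig1 at −0.96 ± 0.04 and Fdft1 at −0.93 ± 0.04. Cell cycle genes rose in 30 of 35 cases, with 0 falling and 5 not passing (31 adjusted over the list alone, adjusted p = 2.18e-11), among them Mcm4 (0.79 ± 0.04), Ccnd1 (0.76 ± 0.04) and Rrm2 (0.69 ± 0.04). P53 targets rose in 11 of 17 cases, with 0 falling and 6 not passing (11 adjusted over the list alone, adjusted p = 3.59e-05), including Cdkn1a (1.199 ± 0.053) and Plk2 (0.99 ± 0.05). Immediate early genes had 14 up, 4 down and 8 not passing of 26 (19 adjusted over the list alone, adjusted p = 0.000203), with Ier3 at 2.53 ± 0.10 and Egr2 at 1.51 ± 0.06. Wnt targets had 6 up, 0 down and 4 not passing of 10 (6 adjusted over the list alone, adjusted p = 0.000982), with Rnf43 at 1.94 ± 0.13. OPC markers had 1 up, 9 down and 6 not passing of 16 (10 adjusted over the list alone, adjusted p = 0.00431), with C1ql1 at −0.92 ± 0.09 and Sox8 at −0.63 ± 0.04. BAF subunits without Smarcc1 had 0 up, 14 down and 15 not passing of 29 (14 adjusted over the list alone, adjusted p = 0.00272), among them the neuronal subunit gene Actl6b (−1.42 ± 0.18) and Bcl11a (−0.59 ± 0.10). Synaptic adhesion genes had 4 up, 11 down and 10 not passing of 25 (17 adjusted over the list alone, adjusted p = 0.0143), among them Cadm3 (−0.52). With exchanged control labels both these lists are lost, BAF subunits at 6 up, 8 down and adjusted p = 0.531 and synaptic adhesion at 0.344. Rnf43 (0.15) and Cadm3 (−0.04) then lose the call, and Ier3 (1.53), Egr2 (0.86) and Bcl11a (−0.39) shrink.

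Microglial transcripts were lower in the hippocampal knockout: 2 rose, 7 fell and 6 did not pass of 15 (10 adjusted over the list alone, camera adjusted p = 0.0121), among them the signaling adaptor gene Tyrobp (−1.97 ± 0.17), the protease gene Ctss (−1.58 ± 0.08) and C1qc (−1.27 ± 0.11). With exchanged control labels the list misses the threshold at adjusted p = 0.109, though 7 genes still fall and the median goes from −0.502 to −0.562, with Tyrobp at −1.2, Ctss at −1.03 and C1qc at −0.73. Heat shock genes, 6 up, 0 down and 4 not passing of 10 (adjusted p = 0.0166), are lost at adjusted p = 0.0611 with an estimated correlation and at 0.0758 with exchanged labels; Hsph1 rose by 0.64 ± 0.05. Integrated stress genes, 12 up, 5 down and 6 not passing of 23 (19 adjusted over the list alone, adjusted p = 0.0341), are lost at adjusted p = 0.128 with an estimated correlation and at 0.108 with exchanged labels. In that list Hspa5 rose by 0.60 ± 0.05 while the cystine transporter gene Slc7a11 fell by −1.33 ± 0.12. Ribosomal protein genes, 1 up, 14 down and 66 not passing of 81 (6 adjusted over the list alone, adjusted p = 0.00953), are lost at adjusted p = 0.702 with an estimated correlation. With exchanged labels they have 0 up and 76 down, their median going from −0.098 to −0.361 (0.179 with an estimated correlation). Astrocyte genes split, with 5 up, 6 down and 4 not passing of 15 (adjusted p = 0.975), a median of −0.14 and a mean of 0.29: Gfap and Agt (2.06 ± 0.13) rose while Aldh1l1 fell (−0.76 ± 0.06). Under exchange Aldh1l1 turns to 0.17, and Agt (0.86) and Slc7a11 (−0.62) shrink. Autism risk genes had 9 up, 12 down and 26 not passing of 47 (22 adjusted over the list alone, adjusted p = 0.546), Notch 2, 5 and 6 of 13 (0.0568), and forebrain regional factors 4, 9 and 4 of 17 (0.313). Glutamate receptors had 3 up, 5 down and 16 not passing of 24 (0.377), GABA receptors 5, 2 and 9 of 16 (0.584), and myelin 4, 8 and 5 of 17 (0.279).

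Cholesterol synthesis genes fell and cell cycle genes rose in both regions. Of genes passing in both, 3186 of 3577 (89.1%) moved the same way and 391 opposite ways. By Fisher's exact test 1722 rose in both against 730.8 expected (odds ratio 7.42, log10 p = −440.3), and 1464 fell in both against 681.7 expected (5.17, p = 3.65e-289). Without knockout mPFC library 3 the latter odds ratio is 3.2. The correlation of both effects across genes is 0.35 (rank correlation 0.451), or 0.571 with exchanged control labels, and genes are not independent replicates. An average of both knockout effects, added after the data were seen, passed for 7607 genes, 3758 up and 3849 down. In it Scg2 rose by 4.89 ± 0.06, Vgf by 4.05 ± 0.07 and Egr1 by 2.30 ± 0.03, and the Notch pathway genes Hes5 (−1.90 ± 0.10), Dll3 (−1.58 ± 0.07) and Dll1 (−1.11 ± 0.04) fell. Of 24 cholesterol synthesis genes all 24 fell (24 adjusted over the list alone, adjusted p = 6.69e-18), and cell cycle genes had 29 up, 0 down and 6 not passing of 35 (29 adjusted over the list alone, adjusted p = 3.41e-12). OPC markers had 3 up, 13 down and 0 not passing of 16 (16 adjusted over the list alone, adjusted p = 0.000331). Immediate early genes (15, 4 and 7 of 26, 0.000138), p53 targets (10, 0 and 7 of 17, 0.000145), Wnt targets (7, 1 and 2 of 10, 0.00145) and heat shock genes (8, 0 and 2 of 10, 0.00202) rose. Integrated stress (14, 4 and 5 of 23, 0.00324), synaptic adhesion (4, 15 and 6 of 25, 0.0217), astrocyte (10, 3 and 2 of 15, 0.0217) and ribosomal protein genes (2, 42 and 37 of 81, 7.4e-05) are lost at adjusted p = 0.0536, 0.0592, 0.0697 and 0.51 with an estimated correlation. The Notch list as a whole did not pass, at 3 up, 6 down and 4 not passing of 13 (adjusted p = 0.179), with a median of 0.06 and a mean of −0.35.

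**Figure D2:**
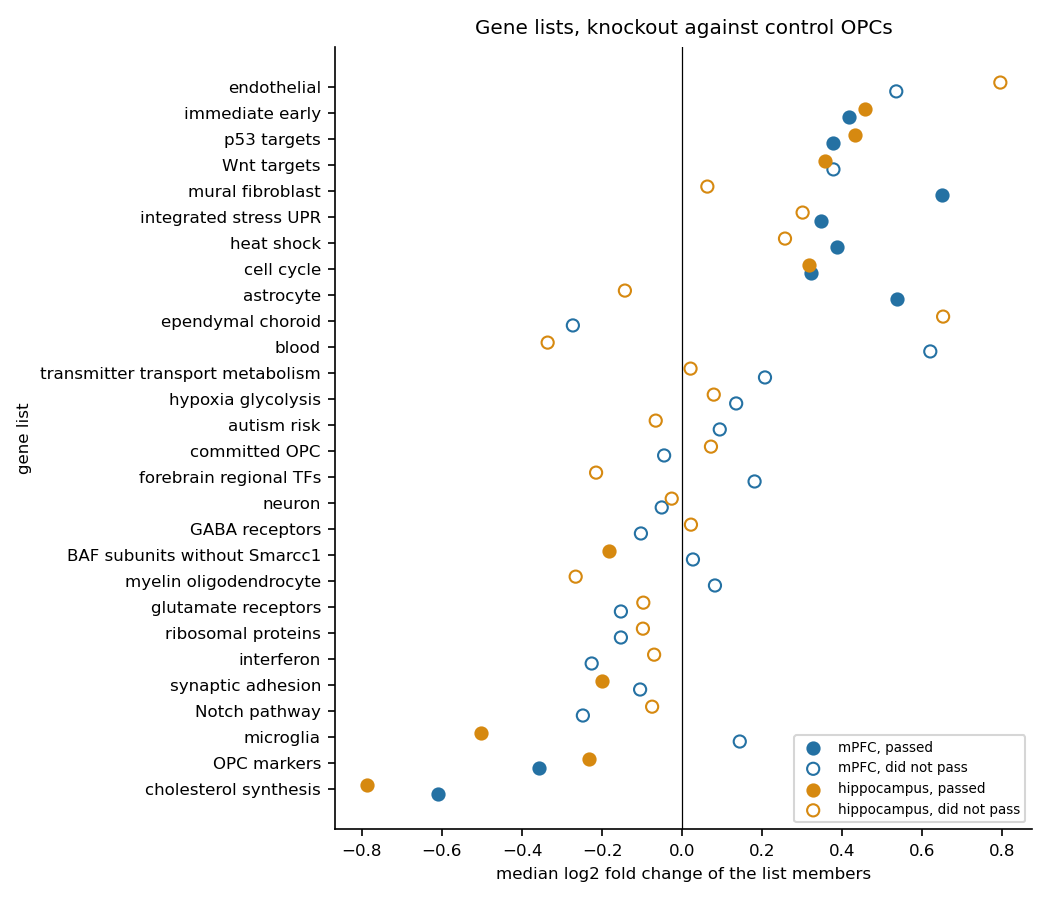
Median log2 fold change (x axis) of each gene list (y axis), knockout against control, in acute mPFC (blue) and acute hippocampus (orange). Each point is 1 list in 1 region, filled where its adjusted p is under 0.05 with an estimated correlation; cholesterol synthesis lies lowest at −0.61 and −0.79.

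The knockout effect differed between regions for Dlx1, Gad1 and Nr2f2, and these differences depend on the region labels of the control groups. Dlx1, a homeobox gene of ventral forebrain and interneurons, rose in the knockout mPFC (2.41 ± 0.18) and fell in the knockout hippocampus (−2.51 ± 0.18), a difference of −4.91 ± 0.26 (chromosome 2: 71,528,113 to 71,533,981, plus strand). Gad1, which makes GABA, did the same (1.62 ± 0.10 and −1.72 ± 0.10), while Nr2f2, an orphan nuclear receptor gene of forebrain patterning, fell in the mPFC (−1.34 ± 0.10) and rose in the hippocampus (1.47 ± 0.10). With those labels exchanged the differences go to 0.31 ± 0.25 for Dlx1, 0.33 ± 0.13 for Gad1 and 0.22 ± 0.14 for Nr2f2, and none of the 3 passes in either region. Forebrain regional factors as a list did not pass, at 4 up, 8 down and 5 not passing of 17 (12 adjusted over the list alone, adjusted p = 0.104). The myelin gene Mag rose by 1.67 ± 0.08 in the mPFC and less in the hippocampus, a difference of −1.45 ± 0.11 that goes to 0.74 ± 0.11 with exchanged labels. Of 13,985 genes 3415 differed, 1650 toward the hippocampus and 1765 toward the mPFC, and without knockout mPFC library 3 the count is 5283. With control labels exchanged 1929 differ, and of the 3415 only 201 keep call and direction while 473 turn direction. Microglia genes differed toward lower in the hippocampus, with 0 up, 7 down and 8 not passing of 15 (7 adjusted over the list alone, camera adjusted p = 0.00019), among them Tyrobp (−2.36 ± 0.24), and with exchanged labels the list is lost at adjusted p = 0.0845 and Tyrobp is at −0.83. Cholesterol synthesis as labelled differed the same way, 0 up, 11 down and 13 not passing of 24 (13 adjusted over the list alone, adjusted p = 0.00019), among them Dhcr7 (−0.55 ± 0.07) and Lss (−0.42 ± 0.05). With exchanged labels that list is lost at adjusted p = 0.133, Dhcr7 loses the call (0.02), Lss turns to 0.28 ± 0.05, and the list medians of −0.61 in mPFC and −0.79 in hippocampus become −0.697 and −0.669. Which region lost more is therefore not settled. Astrocyte genes (2, 10 and 3 of 15, 0.0202), mural and fibroblast genes (0, 6 and 7 of 13, 0.0184) and BAF subunits (0, 6 and 23 of 29, 0.00367) are each lost at adjusted p = 0.0898 with an estimated correlation. With exchanged labels astrocyte genes and cell cycle genes (0 up, 12 down) pass even so (0.04 each), BAF subunits are lost at adjusted p = 0.26, and mural genes at 0.564, their median turning from −0.899 to 0.308. Transport and metabolism genes (3 up, 7 down, 9 not passing of 19, 11 adjusted over the list alone, adjusted p = 0.0462) are lost at adjusted p = 0.218 with an estimated correlation, at 0.0686 under quantile normalization and at 0.771 with exchanged labels. Committed OPC genes, 7 up, 4 down and 4 not passing of 15 (adjusted p = 0.0545), pass under quantile normalization (0.0416) and, with 10 up and 0 down, under exchanged labels (3.08e-10, and 0.00272 with an estimated correlation).

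As labelled, control OPCs of the hippocampus carried more Dlx1 (2.61 ± 0.18), Dlx2 (3.06 ± 0.23) and Gad1 (1.84 ± 0.10) than control OPCs of the mPFC, and less Zic1 (−1.30 ± 0.09) and Nr2f2 (−1.30 ± 0.10). An exchange of the labels would turn every direction in this paragraph. Forebrain regional factors as a list did not pass, at 8 up, 4 down and 5 not passing of 17 (adjusted p = 0.144). The matrix genes Fbln2 (1.14 ± 0.07) and Tnc (1.00 ± 0.04) were higher too. Lower were Alb (−3.86 ± 0.50, adjusted p = 9.88e-05), Gfap (−1.41 ± 0.06, adjusted p = 2.28e-09), Pxdc1 (−1.15) and Pnlip (−1.01). In all 3313 genes passed, 1705 up and 1608 down, and the count is 2111 without control hippocampus library 2 and 2199 without control mPFC library 2. Cholesterol synthesis was higher in the hippocampus, with 11 up, 1 down and 12 not passing of 24 (14 adjusted over the list alone, camera adjusted p = 0.000383), among them Lss (0.35 ± 0.04). Ribosomal protein genes, 0 up, 57 down and 24 not passing of 81 (62 adjusted over the list alone, adjusted p = 1.55e-23), are lost at adjusted p = 0.144 with an estimated correlation. Autism risk genes (13 up, 5 down, 29 not passing of 47, 23 adjusted over the list alone, adjusted p = 0.00424) are lost at adjusted p = 0.225 with an estimated correlation. BAF subunits (7 up, 0 down, 22 not passing of 29, 7 adjusted over the list alone, adjusted p = 0.00459) are lost at adjusted p = 0.138 with an estimated correlation. Myelin (6 up, 1 down, 10 not passing of 17, adjusted p = 0.0352), microglia (6, 0 and 9 of 15, 0.0482), mural (3, 0 and 10 of 13, 0.0316) and blood (2, 0 and 4 of 6, 0.0352) are each lost at adjusted p = 0.138 with an estimated correlation. Ependymal genes (1, 3 and 2 of 6, 0.0439) are lost at adjusted p = 0.138 with an estimated correlation and at 0.0663 under quantile normalization. Transport genes (4, 0 and 15 of 19, 0.0482) are lost at adjusted p = 0.225 with an estimated correlation and at 0.0814 under quantile normalization.

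Among knockout OPCs these 5 regional genes ran the other way. The hippocampus had less Dlx1 (−2.30 ± 0.18), Dlx2 (−2.19 ± 0.23) and Gad1 (−1.50 ± 0.10) than the mPFC, and more Nr2f2 (1.51 ± 0.10) and Zic1 (0.96 ± 0.09), while the list of forebrain regional factors did not pass (3, 5 and 9 of 17, adjusted p = 0.283). Lyz2 (−1.59 ± 0.06), Fbln2 (−1.42 ± 0.07), Gpnmb (−1.09), Aldh1l1 (−1.05 ± 0.06) and the collagen chaperone gene Serpinh1 (−1.01) were lower, and Bche (0.98 ± 0.10) higher. In all 2114 genes passed, 1139 up and 975 down. The count depends on single libraries of either group: without knockout mPFC library 1, 2 or 3 it is 1051, 1045 and 4922, and without knockout hippocampus library 4, 5 or 6 it is 1055, 1067 and 1128. Committed OPC genes were higher, with 11 up, 0 down and 4 not passing of 15 (11 adjusted over the list alone, camera adjusted p = 5.78e-10), among them the sialidase gene Neu4 (0.65 ± 0.05), Nkx2-2 (0.55 ± 0.06) and Gpr17 (0.40 ± 0.04). Microglia genes were lower, with 0 up, 6 down and 9 not passing of 15 (10 adjusted over the list alone, adjusted p = 5.76e-06), among them Tyrobp (−1.60 ± 0.17). Astrocyte genes were lower, with 1 up, 8 down and 6 not passing of 15 (10 adjusted over the list alone, adjusted p = 5.76e-06). Cell cycle genes were lower, with 0 up, 7 down and 28 not passing of 35 (9 adjusted over the list alone, adjusted p = 0.00021). So were integrated stress genes, with 0 up, 5 down and 18 not passing of 23 (13 adjusted over the list alone, adjusted p = 0.000689). Heat shock genes (0 up, 3 down, 7 not passing of 10, 4 adjusted over the list alone, adjusted p = 0.0134) are lost at adjusted p = 0.0723 with an estimated correlation and at 0.0584 under quantile normalization. Ribosomal protein genes (0 up, 39 down, 42 not passing of 81, 55 adjusted over the list alone, adjusted p = 9.5e-19) are lost at adjusted p = 0.211 with an estimated correlation.

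The regional differences of control and knockout OPCs run opposite ways for most shared genes. Of 786 genes passing in both, 548 have opposite signs and 238 (30.3%) the same, and the correlation across genes is −0.279 (rank correlation −0.175). Genes lower in the hippocampus are nevertheless shared beyond chance, 164 against 112.1 expected (odds ratio 1.62, p = 1.84e-07 by Fisher's exact test), and genes higher are not, 74 against 138.9 (0.48). Untreated cultures of the same regions give an outside axis, chosen after the data were seen, with region not separated from table or culture batch. On it control mPFC libraries score 0.078, 0.117 and 0.117 and control hippocampus libraries −0.323, −0.292 and −0.181, so all 9 pairs have the mPFC library nearer the hippocampus culture. Knockout mPFC libraries score −0.184, −0.19 and −0.01 and knockout hippocampus libraries 0.302, 0.287 and 0.28, so all 9 pairs keep the labelled order. Across 10,864 genes the correlation with the culture difference is −0.35 for control and 0.427 for knockout, with genes not independent replicates. The groups were kept as labelled throughout.

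**Figure D3:**
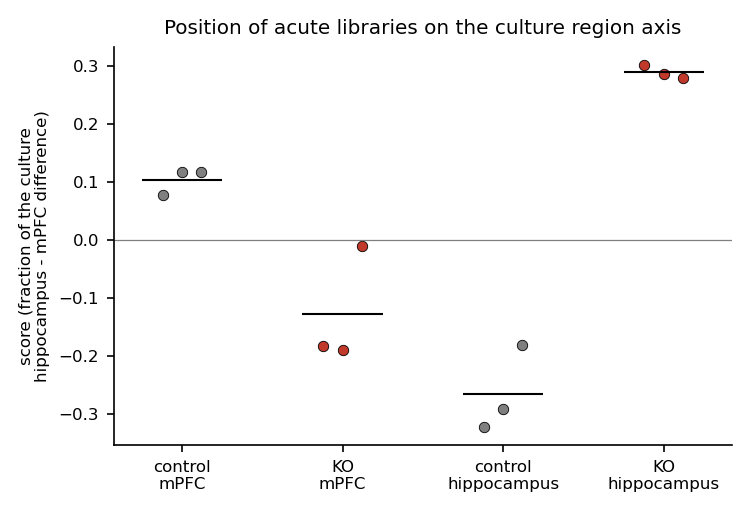
Score of each acute library on the axis from untreated mPFC culture to untreated hippocampus culture (y axis, fraction of the culture difference) by genotype and region. Points are single libraries and lines group means: 0.104 and −0.265 for control mPFC and hippocampus, −0.128 and 0.289 for knockout mPFC and hippocampus.

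Other measured features of the acute libraries belong beside these gene groups. Y-linked transcripts were higher in knockout libraries of both regions: Ddx3y, an RNA helicase gene, stood at 98.2 (control mPFC), 406.8 (knockout mPFC), 189.5 (control hippocampus) and 450.1 (knockout hippocampus), with adjusted p = 7.02e-09 and 1.56e-06. Kdm5d (2.19 and 0.95) and Eif2s3y (2.12 and 1.00) moved alike. X-linked partners moved less: Ddx3x (0.01, 0.08), Eif2s3x (0.01, 0.19), Kdm5c (−0.09, −0.28). Alb stood at 71.5 ± 44.3 in control and 167.2 ± 146.8 in knockout hippocampus, so its mPFC fall comes from a high control level. Knockout mPFC library 3 and control hippocampus library 3 stand apart from their replicates, with a mean squared deviation per gene of 17.2 and 10.82 times that of counting noise, where control mPFC libraries reach 2.52. The complement gene C1qa, made by microglia, stood at 93.8, 90.6, 155.1 and 68.6 in control mPFC, knockout mPFC, control hippocampus and knockout hippocampus.

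GABA raised Atf5, Slc7a11 and Slc7a5 in cultured mPFC OPCs. Atf5, a transcription factor gene of the integrated stress response, went from 272 ± 9.5 to 724 ± 88.7 (1.40 ± 0.08, adjusted p = 2.09e-09; chromosome 7: 44,812,256 to 44,816,658, minus strand). The cystine transporter gene Slc7a11 went from 466.5 ± 22.6 to 945.1 ± 21.8 (1.02 ± 0.06), and Serpinh1 (1.01 ± 0.05), H1f2 (0.89), Slc7a5 (0.83 ± 0.04), Mest (0.82), Fbln2 (0.81) and Igfbp2 (0.63) rose. Gpnmb fell from 1525.9 to 854.9 (−0.84 ± 0.06), as did Frmd4a (−0.61), Cdk18 (−0.51) and the potassium channel gene Kcnq3 (−0.48). Of 14,894 genes 975 passed, 474 up and 501 down. Without untreated library 1, 2 or 3 the count is 448, 418 and 433, without GABA library 1 it is 1820, and with no filter on low values it is 641. The test is limma-trend on 3 against 3 libraries, and GABA library 1 varies most, with a mean squared deviation per gene of 6.34 times that of counting noise.

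Cholesterol synthesis genes fell with GABA in the mPFC culture, 0 up, 15 down and 9 not passing of 24 (20 adjusted over the list alone, camera adjusted p = 3.9e-16), a group that includes Idi1 (−0.36 ± 0.05). Hmgcs1, which makes the sterol precursor HMG-CoA, went from 21,323 ± 9.2 to 17,861.2 ± 480.1 (−0.26 ± 0.03). Committed OPC genes fell, 0 up, 7 down and 8 not passing of 15 (10 adjusted over the list alone, adjusted p = 1.99e-07), among them Enpp6 (−0.26 ± 0.04) and Sirt2 (−0.21 ± 0.03). Integrated stress genes rose, 11 up, 3 down and 9 not passing of 23 (18 adjusted over the list alone, adjusted p = 6.35e-07), among them Slc3a2 (0.60 ± 0.04) and the serine synthesis gene Phgdh (0.42 ± 0.04). Myelin genes (1 up, 6 down, 9 not passing of 16, 10 adjusted over the list alone, adjusted p = 0.00587) include Mag (−0.40 ± 0.06) and are lost at adjusted p = 0.104 with an estimated correlation. P53 targets (6 up, 0 down, 9 not passing of 15, 8 adjusted over the list alone, adjusted p = 0.000422) are lost at adjusted p = 0.0884 with an estimated correlation. Hypoxia and glycolysis genes (4 up, 0 down, 13 not passing of 17, 6 adjusted over the list alone, adjusted p = 7.23e-05) are lost at adjusted p = 0.104 with an estimated correlation. Glutamate receptors (0 up, 3 down, 19 not passing of 22, 4 adjusted over the list alone, adjusted p = 0.00642) include Grin3a (−0.23) and are lost at adjusted p = 0.104 with an estimated correlation. Synaptic adhesion (0, 3 and 22 of 25, 0.00247) is lost at adjusted p = 0.102 with an estimated correlation. Astrocyte genes (6, 2 and 5 of 13, 0.00216) and cell cycle genes (1, 1 and 33 of 35, 0.009) are lost at adjusted p = 0.228 with an estimated correlation. Mitochondrially encoded genes (0, 1 and 12 of 13, 0.00247) are lost at adjusted p = 0.182 with an estimated correlation. Autism risk genes (0, 4 and 42 of 46, 0.0169) are lost at adjusted p = 0.374 with an estimated correlation and at 0.106 under quantile normalization. GABA receptors had 0 up, 1 down and 14 not passing of 15 (0.181), and BAF subunits 0, 0 and 29 of 29.

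GABA in hippocampal OPC cultures raised Serpina3n, a secreted protease inhibitor gene, from 151.1 ± 13.5 to 460 ± 34 (1.60 ± 0.08, adjusted p = 1.66e-13; chromosome 12: 104,406,729 to 104,414,329, plus strand) and Cdkn1a from 339.2 to 621.7 (0.87 ± 0.07). Lyz2 went from 2510.7 to 1356.5 (−0.89 ± 0.04), and Mpeg1, a perforin gene of macrophages, fell by −0.94 ± 0.07. H1f2 (0.96), Gnas (0.98 ± 0.09), Igfbp2 (0.88), Fn1 (0.83) and Nnat (0.74) rose, and Hmgn5 (−0.77), Cfdp1 (−0.49) and Gpnmb (−0.48) fell. Rpl23a (0.86) also passed but loses the call under robust empirical Bayes, and sharing of its reads with near copies was not measured. Obp1a, an odorant-binding protein gene, is listed at 266.8, 639.1 and 687.7 in untreated hippocampus libraries and at 0 with GABA, and at 611.5 in 1 mPFC library with GABA, so it is given without a fold change. Of 14,933 genes 3685 passed, 1781 up and 1904 down, and 2357 without GABA library 2. The test is limma-trend on 3 against 3 libraries.

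No list passed in the hippocampus culture once the correlation was estimated. Microglia genes (0 up, 6 down, 6 not passing of 12, 7 adjusted over the list alone, camera adjusted p = 0.000339) include Ctss (−0.75 ± 0.08), C1qb (−0.67 ± 0.11) and C1qc (−0.60 ± 0.12), and are lost at adjusted p = 0.107 with an estimated correlation. Immediate early genes (12 up, 0 down, 12 not passing of 24, 12 adjusted over the list alone, adjusted p = 0.000134) include the activity-regulated gene Npas4 (2.50 ± 0.31) and Fosl2 (0.83 ± 0.12), and are lost at adjusted p = 0.105 with an estimated correlation. P53 targets (10 up, 1 down, 5 not passing of 16, 11 adjusted over the list alone, adjusted p = 9.38e-05) are lost at adjusted p = 0.105 with an estimated correlation. Integrated stress genes (12 up, 6 down, 6 not passing of 24, 18 adjusted over the list alone, adjusted p = 0.00902) include Slc7a5 (0.58 ± 0.04) and Asns (0.34 ± 0.04). Cholesterol synthesis genes (8 up, 0 down, 16 not passing of 24, 8 adjusted over the list alone, adjusted p = 0.00902) include Dhcr7 (0.33 ± 0.04) and Mvd (0.31 ± 0.04). Both lists are lost at adjusted p = 0.231 with an estimated correlation, as are mural genes (4, 0 and 5 of 9, 0.00902), hypoxia (6, 0 and 11 of 17, 0.00471) and Wnt targets (3, 0 and 7 of 10, 0.027). Autism risk genes (2 up, 14 down, 31 not passing of 47, 20 adjusted over the list alone, adjusted p = 0.00902) are lost at adjusted p = 0.231 with an estimated correlation and at 0.0783 under quantile normalization. Mitochondrially encoded genes had 4 up, 7 down and 2 not passing of 13 (0.0665), and GABA receptors 2, 4 and 8 of 14 (0.337).

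The GABA response of sterol genes differed between the cultured regions. Hmgcs1 fell in the mPFC culture and rose in the hippocampus culture (0.12 ± 0.03, from 20,158.7 to 21,852.5), a difference of 0.37 ± 0.04, and Dhcr7 (0.50 ± 0.06) and Mvd (0.43 ± 0.06) differed alike (Hmgcs1 at chromosome 13: 119,690,379 to 119,708,260, plus strand). Of 24 cholesterol synthesis genes 16 were higher, 0 lower and 8 not passing (21 adjusted over the list alone, camera adjusted p = 1.1e-21). Myelin genes differed toward the hippocampus, 4 up, 0 down and 13 not passing of 17 (6 adjusted over the list alone, adjusted p = 0.00148), with Mag at 0.49 ± 0.07 and Mbp at 0.38 ± 0.07. Microglia genes differed toward the mPFC, 0 up, 2 down and 11 not passing of 13 (5 adjusted over the list alone, adjusted p = 0.000374). Slc7a11 responded less in the hippocampus (−0.82 ± 0.08). Committed OPC genes (3, 0 and 12 of 15, 0.00467) are lost at adjusted p = 0.0856 with an estimated correlation. Immediate early genes (4, 0 and 20 of 24, 0.000496) are lost at adjusted p = 0.146 with an estimated correlation, and Wnt targets (1, 0 and 9 of 10, 0.0122) at adjusted p = 0.293 with an estimated correlation. Integrated stress genes (1, 3 and 20 of 24, 0.0425) are lost at adjusted p = 0.147 with an estimated correlation and at 0.0639 under quantile normalization.

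Genes passing in both cultured regions otherwise moved together, 509 of 543 (93.7%) with the same sign. By Fisher's exact test there are 257 up against 56.9 expected (odds ratio 10.04, p = 6.19e-115) and 252 down against 63.9 expected (7.9, p = 1.14e-96). The odds ratio for genes up is 16.23 without mPFC untreated library 1. That for genes down is 12.04, 12.73 and 13.87 without mPFC untreated library 1, 2 or 3, and 12.03 and 5.1 without mPFC GABA library 1 or 2. The correlation across genes is 0.338, with genes not independent replicates. Of 15,487 genes 741 differed in their response, 402 toward the hippocampus and 339 toward the mPFC. The count is 348, 270 and 328 without hippocampus GABA library 1, 2 or 3, and 1116, 310 and 321 without hippocampus untreated library 1, 2 or 3. It is 483 and 1278 without mPFC GABA library 1 or 2, and 340, 351 and 269 without mPFC untreated library 1, 2 or 3. The test compares differences taken inside separately normalized tables.

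**Figure D4:**
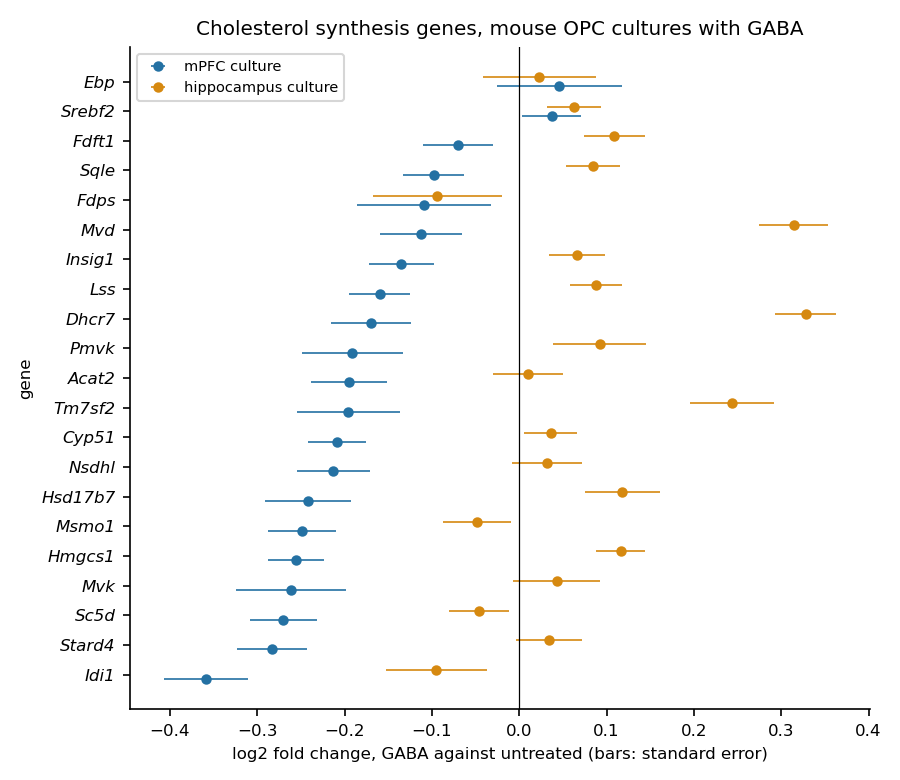
Log2 fold change with GABA (x axis) of cholesterol synthesis genes (y axis) in mouse mPFC culture (blue) and hippocampus culture (orange). Each point is 1 gene in 1 culture with its standard error; Hmgcs1 lies at −0.26 and 0.12.

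Rat cortex OPCs answered GABA with more integrated stress and myelin transcripts and with fewer cell cycle transcripts. Serpinh1 went from 384.4 ± 10.4 to 837 ± 13.5 (1.12 ± 0.05, adjusted p = 2.36e-17), and the asparagine synthetase gene Asns (0.96 ± 0.05), Igfbp3 (0.95) and Cdkn1a (0.85 ± 0.06) rose. Glul, which turns glutamate into glutamine, went from 7810.8 ± 289.2 to 5531.3 ± 70 (−0.50 ± 0.03, adjusted p = 3.07e-15), and Hes5 (−0.43) and Id3 (−0.40) fell. Of 12,481 genes 2957 passed, 1480 up and 1477 down, with 91 and 9 at least 2-fold. Integrated stress genes rose, 16 up, 1 down and 6 not passing of 23 (18 adjusted over the list alone, camera adjusted p = 4.03e-16), among them Slc7a11 (2.32 ± 0.12) and Slc7a5 (0.60 ± 0.03). Microglia genes rose, 11 up, 0 down and 1 not passing of 12 (11 adjusted over the list alone, adjusted p = 1.49e-14), with C1qa going from 65.4 ± 5.7 to 172.3 ± 12.8 and C1qc rising by 1.87 ± 0.15. Myelin genes rose, 10 up, 0 down and 8 not passing of 18 (12 adjusted over the list alone, adjusted p = 2.68e-11), with Mbp going from 70,676.7 ± 2492.2 to 90,615.6 ± 2050.1 (0.36 ± 0.03). Cell cycle genes fell, 0 up, 22 down and 11 not passing of 33 (29 adjusted over the list alone, adjusted p = 3.36e-13), among them Birc5 (−0.33) and the ubiquitin-conjugating enzyme gene Ube2c (−0.40). The test is limma-trend on 3 against 3 libraries.

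Ribosomal protein genes fell with GABA in rat, 0 up, 58 down and 6 not passing of 64 (60 adjusted over the list alone, camera adjusted p = 2.17e-28), among them Rps16 (−0.28), but the list is lost at adjusted p = 0.198 with an estimated correlation. Transport and metabolism genes (12 up, 1 down, 6 not passing of 19, 14 adjusted over the list alone, adjusted p = 1.33e-05) include the glutamate transporter gene Slc1a3 (0.26) and are lost at adjusted p = 0.152 with an estimated correlation. GABA receptors (4 up, 0 down, 8 not passing of 12, 4 adjusted over the list alone, adjusted p = 0.0298) include Gabbr2 (0.32) and Gabbr1 (0.12), and are lost at adjusted p = 0.238 with an estimated correlation. P53 targets (9 up, 1 down, 7 not passing of 17, 12 adjusted over the list alone, adjusted p = 2.5e-05) are lost at adjusted p = 0.0614 with an estimated correlation. Immediate early (7, 2 and 13 of 22, 0.0164) and hypoxia genes (5, 0 and 11 of 16, 0.0182) are lost at adjusted p = 0.198 with an estimated correlation. Mitochondrially encoded genes (0, 9 and 4 of 13, 2.87e-05) are lost at adjusted p = 0.355 with an estimated correlation, and autism risk genes (9, 2 and 35 of 46, 0.0482) at adjusted p = 0.622 with an estimated correlation. Committed OPC genes (7, 5 and 3 of 15, 0.0356) are lost at adjusted p = 0.198 with an estimated correlation and at 0.0954 under quantile normalization. Cholesterol synthesis did not pass, with 2 up, 2 down and 19 not passing of 23 (0.899).

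Glutamate lowered committed OPC and myelin genes in rat OPCs and raised integrated stress genes and p53 targets. Egfr, a growth factor receptor gene, went from 215.8 ± 9.8 to 650.3 ± 24.4 (1.59 ± 0.06, adjusted p = 8.79e-35) and Cdkn1a from 382.9 ± 10.5 to 1072.2 ± 49.7 (1.48 ± 0.05, adjusted p = 1.45e-39). Gpnmb (1.18 ± 0.06), Mmp2 (1.03), Cst3 (1.01 ± 0.02), Asns (0.98 ± 0.05) and the heme oxygenase gene Hmox1 (0.86) rose. The proteoglycan gene Acan (−0.77 ± 0.05), Mreg (−0.71), Aldh1l1 (−0.61) and the NMDA receptor gene Grin3a (−0.58 ± 0.05) fell. Of 12,465 genes 3524 passed, 1753 up and 1771 down, with 64 and 25 at least 2-fold. Committed OPC genes fell, 0 up, 14 down and 1 not passing of 15 (14 adjusted over the list alone, camera adjusted p = 1.12e-24), among them Gpr17 (−0.52 ± 0.02), Fyn (−0.35 ± 0.02) and Sirt2 (−0.33 ± 0.02). Myelin genes fell, 0 up, 9 down and 11 not passing of 20 (9 adjusted over the list alone, adjusted p = 3.79e-11), with Mag going from 6067.7 ± 199.2 to 4257.2 ± 123.9 (−0.51 ± 0.03). Integrated stress genes rose, 17 up, 0 down and 5 not passing of 22 (17 adjusted over the list alone, adjusted p = 2.41e-19), among them Slc7a1 (0.55). P53 targets rose, 12 up, 1 down and 4 not passing of 17 (14 adjusted over the list alone, adjusted p = 1.09e-10), among them Ccng1 (0.52) and Eda2r (1.02). Cholesterol synthesis fell, 1 up, 15 down and 7 not passing of 23 (17 adjusted over the list alone, adjusted p = 3.16e-08). Forebrain regional factors rose, 14 up, 0 down and 3 not passing of 17 (14 adjusted over the list alone, adjusted p = 1.62e-07), among them Etv1 (0.31 ± 0.03) and Lhx2 (0.43 ± 0.05). The test is limma-trend on 3 against 3 libraries.

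Synaptic adhesion genes fell with glutamate, 1 up, 17 down and 7 not passing of 25 (19 adjusted over the list alone, camera adjusted p = 6.91e-09), though the list is lost at adjusted p = 0.0538 with an estimated correlation. Cell cycle genes rose, 21 up, 2 down and 10 not passing of 33 (26 adjusted over the list alone, adjusted p = 4.86e-07), with Ccnd1 at 0.38 ± 0.02. OPC markers fell, 3 up, 10 down and 3 not passing of 16 (13 adjusted over the list alone, adjusted p = 2.25e-05), with Matn4 at −0.56. Both are lost at adjusted p = 0.0538 with an estimated correlation, as are hypoxia genes (10 up, 0 down, 6 not passing of 16, adjusted p = 2.1e-08), led by Vegfa (0.75), and transport genes (9, 6 and 4 of 19, 0.00179), led by Slc1a3 (0.41). Immediate early genes (10 up, 2 down, 8 not passing of 20, 12 adjusted over the list alone, adjusted p = 0.000274) include Fos (0.95) and Jun (0.46) and are lost at adjusted p = 0.05 with an estimated correlation. Astrocyte genes (10, 1 and 3 of 14, 9.57e-06), among them Gja1 (0.59), and BAF subunits (0, 8 and 19 of 27, 0.0187), among them Smarcd1 (−0.17), are lost at adjusted p = 0.0853 with an estimated correlation. Glutamate receptors (1, 9 and 13 of 23, 0.00834) are lost at adjusted p = 0.205 with an estimated correlation. Mitochondrially encoded genes (0, 7 and 6 of 13, 0.00863) are lost at adjusted p = 0.505 with an estimated correlation and at 0.187 under quantile normalization, where Mt-atp8, Mt-nd4 and Mt-nd5 turn direction.

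Set against each other, glutamate and GABA differed in myelin and cell cycle genes of rat OPCs. Myelin genes alone pass in opposite directions with an estimated correlation, up with GABA and down with glutamate. The glutamate effect minus the GABA effect is −0.63 ± 0.03 for Mbp and −0.83 ± 0.04 for Mag, genes of the myelin sheath, and 0.30 ± 0.04 for Ccnd1. Gpnmb (0.88), Cst3 (0.86), Igfbp5 (0.77), the Hippo pathway gene Yap1 (0.71), Egfr (0.69 ± 0.14) and Cdkn1a (0.64 ± 0.08) lean to glutamate, and Ptprt (−1.18 ± 0.08), Lpar1 (−1.12), Tagln (−1.01) and Tmem163 (−1.001) to GABA. Of 12,675 genes 2593 differed, 1267 toward glutamate and 1326 toward GABA. Committed OPC genes had 0 up, 13 down and 2 not passing of 15 (14 adjusted over the list alone, camera adjusted p = 5.53e-23). Myelin had 0 up, 14 down and 6 not passing of 20 (15 adjusted over the list alone, adjusted p = 8.9e-20), and cell cycle 29 up, 0 down and 4 not passing of 33 (30 adjusted over the list alone, adjusted p = 3.32e-21). Cholesterol synthesis had 0 up, 13 down and 10 not passing of 23 (14 adjusted over the list alone, adjusted p = 7.95e-06), and forebrain regional factors 5 up, 0 down and 13 not passing of 18 (5 adjusted over the list alone, adjusted p = 0.00219). Ribosomal protein genes (48 up, 0 down, 16 not passing of 64, 52 adjusted over the list alone, adjusted p = 6.55e-23) are lost at adjusted p = 0.0938 with an estimated correlation. Glutamate receptors (1, 8 and 14 of 23, 0.0015), GABA receptors (1, 5 and 7 of 13, 0.011), heat shock (3, 0 and 6 of 9, 0.0324), p53 targets (7, 1 and 9 of 17, 0.0215) and hypoxia (5, 0 and 11 of 16, 0.000975) are each lost at adjusted p = 0.0938 with an estimated correlation. Synaptic adhesion (1, 13 and 11 of 25, 3.95e-08) is lost at adjusted p = 0.0937 with an estimated correlation. OPC markers (1, 10 and 5 of 16, 0.000423) are lost at adjusted p = 0.0876 with an estimated correlation, and astrocyte genes (6, 2 and 6 of 14, 0.0107) at adjusted p = 0.0952 with an estimated correlation. Microglia (0, 2 and 10 of 12, 0.0398) are lost at adjusted p = 0.0938 with an estimated correlation, and mitochondrially encoded genes (3, 0 and 10 of 13, 0.0376) at adjusted p = 0.5 with an estimated correlation, both also at 0.0507 under median-of-ratios rescaling. Autism risk genes (1, 5 and 40 of 46, 0.045) are lost at adjusted p = 0.403 with an estimated correlation and at 0.138 under quantile normalization.

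The transmitters also shared part of their response. Of 12,069 genes tested in both sets 451 rose with each transmitter against 198.2 expected (odds ratio 3.56, p = 3.9e-77 by Fisher's exact test), Serpinh1, Asns and Cdkn1a among them. 330 fell with each against 209.1 expected (1.92, p = 5.42e-20 by Fisher's exact test). Of 1243 genes passing in both, 781 (62.8%) have the same sign and 462 opposite signs, and the correlation across genes is 0.233 (rank correlation 0.161), with genes not independent replicates. The sets have separate untreated controls and were normalized separately, so the comparison rests on differences inside each set, and a difference between the sets of culture is not separated from one between the transmitters.

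**Figure D5:**
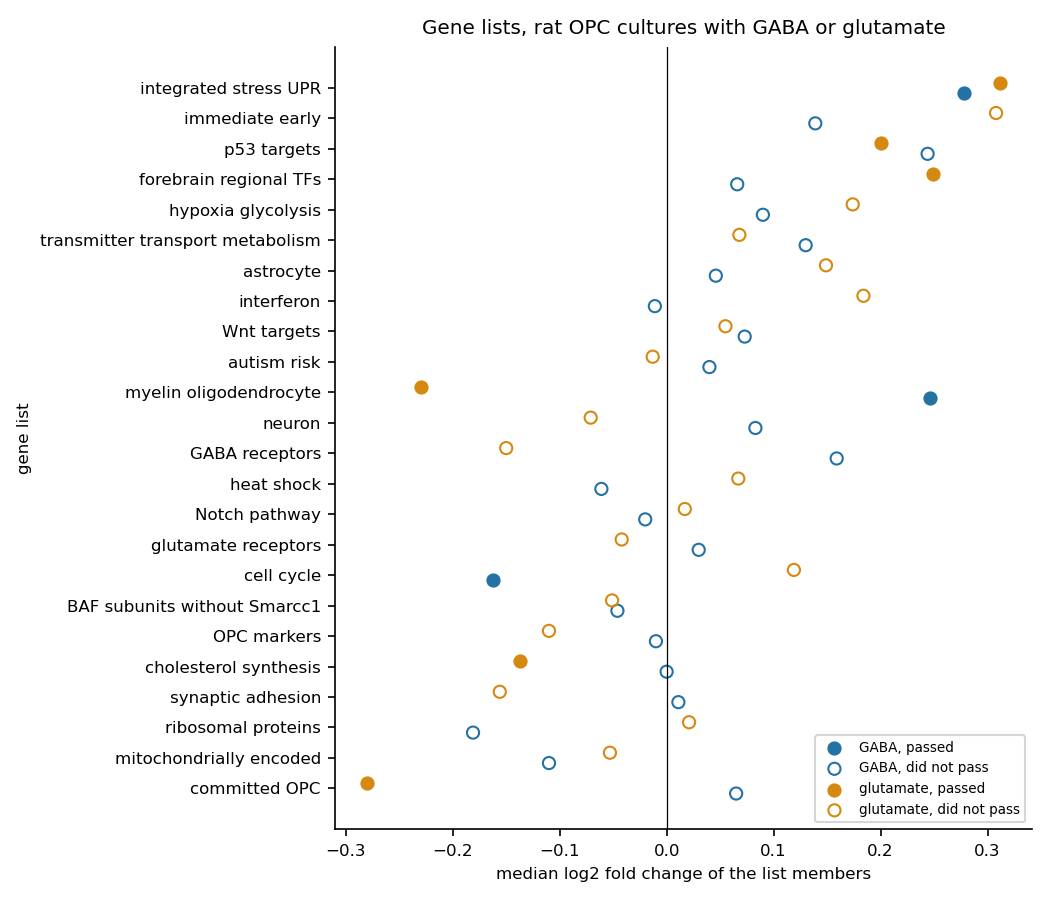
Median log2 fold change (x axis) of each gene list (y axis) in rat cortex OPCs with GABA (blue) and with glutamate (orange), against the untreated cultures of the same set. Each point is 1 list with 1 transmitter, filled where its adjusted p is under 0.05 with an estimated correlation; committed OPC genes lie at 0.065 and −0.28.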

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

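The tests of a mislabelled control region, of fewer microglia, of a fall by 1 common fraction and of a general fall of other cell types were chosen after the results were seen. The tests on libraries standing apart, on GC content and gene length and on other splits of the libraries were written before their results.

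The knockout effect differed between hippocampus and mPFC, by the interaction test, for 3415 genes, of which the largest are listed here as hippocampus minus mPFC on the log2 scale. Toward the hippocampus were Alb (4.25), Pxdc1 (1.65), Pnlip (1.41), Fbln5 (1.39), Pllp (1.38), Hopx (1.34), Tmem100 (1.31) and Eya1 (1.29). Toward the mPFC were Fbln2 (−2.56), Aldh1l1 (−1.99), Gpnmb (−1.99), Lyz2 (−1.59), Mest (−1.57), Nwd1 (−1.53) and Slc6a11 (−1.39). Smarcc1 itself differed by −0.85, so depth of the knockout and region change together. With the control labels exchanged, which was also tried after the results were seen, Smarcc1 differs by −0.45 and most of the 15 genes do not hold. Pllp, Eya1, Tmem100, Fbln2, Aldh1l1, Gpnmb, Mest and Slc6a11 lose the call, and Alb (−3.48), Pxdc1 (−0.66), Pnlip (−0.60), Fbln5 (−0.49) and Hopx (−0.36) turn direction. Nwd1 shrinks to −0.29, and only Lyz2 (−1.58) keeps its size.

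The GABA effect differed between cultures of the regions, by the interaction test, for 741 genes. Toward the hippocampus were Rpl23a (1.26), Gnas (1.24), mt-Co2 (0.84), Spacdr (0.83), Gng3 (0.72), Ssbp4 (0.61), Rps23 (0.61) and Serpina3n (0.61). Toward the mPFC were mt-Nd6 (−1.13), Slc7a11 (−0.82), Hmgn5 (−0.68), Atf5 (−0.68), Itga6 (−0.67), Serpinh1 (−0.64) and Tnc (−0.60). Obp1a reaches −12.03 only because it is listed at 0 in some libraries and at 266.8 to 687.7 in others, and no fold change is claimed for it. Rpl23a, Gnas, mt-Co2, Spacdr, Ssbp4, Rps23, Obp1a, mt-Nd6 and Hmgn5 lose the call under robust empirical Bayes, and Serpina3n loses it with a pseudocount of 0.1. Sharing of reads of Rpl23a and Rps23 with near copies was not measured.

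The regional differences of control and knockout libraries run opposite ways for most shared genes. The region labels of the control groups may be exchanged. As this predicts, 9 of 9 control pairs have the mPFC library nearer the hippocampus culture, while knockout libraries keep the labelled order. At −0.306 without the libraries standing apart, the regional correlation argues against these libraries as the cause. Partly removing GC and length trends (GC correlation 0.228 to 0.134 in control, −0.432 to 0.04 in knockout) leaves −0.289, so these stay open. A reversal of regional identity by Baf155 loss alone would leave control libraries in culture order, which the same 9 pairs oppose. It stays open if culture labels were exchanged, regional genes turn in culture or the axis reflects batch. A preparation batch shared by control hippocampus and knockout mPFC, not tested, stays open, as do exchanged knockout and culture labels. The submitters' sheets would help.

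Microglial transcripts were lower with GABA in the hippocampus culture, though that list is lost at adjusted p = 0.107 with an estimated correlation, and higher with GABA in rat. That 91.7% of tested microglia genes (11 of 12) were lower, with Ctss at 396.2 untreated and 236.3 with GABA and C1qb at 160 and 100, restates the pattern and cannot tell fewer microglia from less transcript per cell. The 12 genes did not all fall by 1 common fraction: they differ by more than their standard errors allow (Cochran Q 68.2). Ctss is at −0.75 ± 0.08 and Csf1r at −0.06 ± 0.12. This does not exclude fewer microglia as the whole cause, because transcript of these genes from other cells would also make the falls unequal. The genes are measured in the same libraries, so Q does not rest on independent values. Whether other non-oligodendrocyte cells fell is not settled. List medians are 0.473 (endothelial, only 3 tested genes, 1 lower), 0.141 (astrocyte, 4 of 14 lower) and 0.009 (neuron, 8 of 17 lower). Fewer microglia, alone or together with changed expression, and a direct effect of GABA on microglial genes stay open. Microglia depletion by immunopanning or sorting against Cd11b would separate them.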

How the results depend on the processing

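The averaged knockout effect, the crossing of control labels, with or without a replicate block, and the removal of both libraries standing apart were chosen after the results were seen; the other settings were planned.

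With region labels as given, 21,792 gene results kept their call status, 197 gained a call, 701 lost one and 3 turned direction. The kept and gained counts do not track direction. The 3 are Mt-atp8 (0.013), Mt-nd4 (0.011) and Mt-nd5 (0.01) in rat glutamate under quantile normalization, all near 0. Smarcc1 ranged from −0.709 to −0.628 in mPFC and from −1.535 to −1.479 in hippocampus as libraries were left out.

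List results depend on the correlation between genes. With it estimated, the lists passing number 9 of 12 in each knockout comparison, 2 for the knockout difference between regions, 7 for the averaged knockout effect, 1 for control region, 5 for knockout region, 3 for GABA in mouse mPFC, 0 for GABA in mouse hippocampus, 3 for the difference in GABA effect, 4 for GABA in rat, 6 for glutamate in rat and 5 for glutamate minus GABA. The cause was not tested.

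With no filter on low values GABA in mouse mPFC calls 641 genes. Without both libraries standing apart (knockout mPFC 3 and control hippocampus 3) control region calls 5896, knockout region 6250 and the knockout difference 6990. The knockout comparisons then call 7960 (mPFC) and 7972 (hippocampus). The cause was not tested, though both libraries have the widest spread.

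Leaving out 1 library at a time, counts ranged from 5599 to 6948 (knockout mPFC), 4624 to 6512 (knockout hippocampus), 2421 without control hippocampus 2 to 5283 without knockout mPFC 3 (knockout difference), 2111 without control hippocampus 2 to 3757 without control hippocampus 3 (control region), and 1045 without knockout mPFC 2 to 4922 without knockout mPFC 3 (knockout region). In culture they ranged from 418 without untreated 2 to 1820 without GABA 1 (GABA, mouse mPFC), 2357 without GABA 2 to 4300 without untreated 1 (GABA, mouse hippocampus), 269 without mPFC untreated 3 to 1278 without mPFC GABA 2 (difference in GABA effect), 2091 to 3113 (GABA, rat), 2859 to 3269 (glutamate, rat) and 2179 to 2714 (glutamate minus GABA). Overlap odds ratios ranged from 5.05 to 9.71 for genes up in both knockout regions and from 3.2 to 6.21 for genes down, from 8.68 to 16.23 for genes up with GABA in both mouse cultures and from 5.1 to 13.87 for genes down, and from 1.82 to 2.2 for genes down with both rat transmitters.

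With control region labels crossed, the knockout mPFC comparison calls 5430 genes and the hippocampus comparison 6733, and the correlation of both effects goes from 0.35 to 0.571. Interaction calls go from 3415 to 1929, and those of at least 2-fold from 492 to 145, with Smarcc1 at −0.858 in mPFC and −1.305 in hippocampus. Crossing turns direction for 91 genes called in mPFC, 93 in hippocampus and 473 of the interaction calls, and 2667, 1752 and 2741 lose the call. Of lists that pass as labelled 2 are lost in mPFC, 5 in hippocampus and 5 for the interaction, while 5, 0 and 9 others pass. In the knockout comparisons this moves more lists than the estimated correlation does. Cholesterol synthesis stays at adjusted p = 3.12e-20 in mPFC and 7.6e-17 in hippocampus. The averaged knockout effect has the same value with either labelling.

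Replicates share only a number. No pair of groups compared as labelled has correlated residuals by number throughout (control and knockout mPFC −0.1 to 0.37, hippocampus −0.15 to −0.03). Control hippocampus and knockout mPFC do, at 0.54, 0.43 and 0.73 for numbers 1, 2 and 3. The crossed mPFC comparison pairs them, and with number as a block it calls 5877 genes rather than 5430, and the crossed hippocampus comparison 7217 rather than 6733. The interaction and the averaged effect hold both groups, and with a block they call 4072 and 7975. Whether these libraries were prepared side by side is not stated, and both libraries number 3 stand apart. Replicate number as a block gives 7183 genes by the titles' numbers and 7069 by the descriptions' in knockout mPFC, 6429 in knockout hippocampus, 1094 and 4105 for GABA in mouse mPFC and hippocampus, and 3175 and 3674 for GABA and glutamate in rat, none over 1.5 times from the value without a block.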

Other observations

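All tests on other splits of the libraries were written before their results were seen.

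Libraries of a comparison were relabelled at random. With 100 splits the knockout difference calls 3415 genes against at most 1565 in any other, the averaged knockout effect 7607 against 2706. The difference in GABA effect calls 741 against 619, and glutamate minus GABA 2593 against 894. These splits mix groups that differ, so chance is not excluded for a difference between effects. The splits also treat libraries as exchangeable. Control hippocampus and knockout mPFC libraries of the same number deviate together, which bears on the knockout difference and the averaged effect. For the simple comparisons there are only 10 splits, too few for a share under 0.05. There the real grouping calls 6622 (knockout mPFC), 5964 (knockout hippocampus), 3313 (control region), 3685 (GABA, mouse hippocampus), 2957 (GABA, rat) and 3524 (glutamate, rat) against at most 0 in any other split, and 2114 (knockout region) and 975 (GABA, mouse mPFC) against at most 1. In all 12 comparisons only the real split calls as many genes.

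In knockout mPFC 54.2% and in knockout hippocampus 54.7% of tested genes have no overlap between groups, where chance alone gives 10%. The share is 41.2% for control region, 32.6% for knockout region, 25.8% and 39.3% for GABA in mouse mPFC and hippocampus, 37.2% for GABA in rat and 38.8% for glutamate in rat.

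Y-linked genes were higher in knockout libraries, Eif2s3y standing at 137.5 and 601.4 in mPFC and at 270.8 and 543.4 in hippocampus, control then knockout. The animals pooled for a library are not described, and no test of sex makeup is reported here. Knockout and sex makeup are therefore not separated for genes that differ between sexes.

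Cdkn1a rose together with cell cycle genes in both knockout regions, from 943 to 2321.3 in mPFC and from 968.4 to 2224.4 in hippocampus, while Ccnd1 rose from 15,221.4 to 29,144.9 and from 16,418.5 to 27,822.3. Cdkn1a is an inhibitor of the kinase that Ccnd1 activates, so transcript levels alone do not say whether the cells divide more. Counting of dividing cells with EdU would answer it.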
